A study of Caenorhabditis elegans with 4 samples.

How the data were processed

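Whole wild-type hermaphrodites were collected, about 200 worms in each group, and RNA was purified as poly(A) RNA with a strand-preserving kit, per the labels' protocols. Per the submitters' processing notes, the tools included Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.10a and featureCounts 2.0.1, and the genome build was ce11 (WBcel235). The order of the tools, the strand setting and the handling of reads that fit several places are not given in the sources used here, so near-identical paralogs and genes overlapping on opposite strands are uncertain. The deposited values are raw counts of reads per gene, whole numbers for 46904 genes in each of 4 tables, per the file headers and the values. Gene names and coordinates are those of the deposited tables. Of the gene identifiers, 46817 were found in Ensembl release 115, which is on the same build, and 68.97% had the same start and end there, so coordinates of the tables are printed and may differ from a current annotation.

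Samples were grouped by their titles, with 2 libraries labelled OP50 and 2 labelled OP50 + MH-1. In all 4 tables the header of the count column names the other group. This was left as found, and every direction rests on the titles. The labels conflict on the age of the worms, on the days of feeding and on whether OP50 was mixed with MH-1.

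Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM factors, and the quasi-likelihood test (glmQLFit and glmQLFTest, package defaults) with the group as the only term. The 12640 genes kept were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are read counts scaled to the TMM-adjusted library size. With totals between 15771890 and 21572225 counts, 3 counts correspond to between 0.139 and 0.190 CPM, and this floor covers counting error only. The biological coefficient of variation was 0.135. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 10.1 over genes with at least 20 counts per pair), so none was treated as a repeat. With 2 libraries in each group no exact permutation test of the groups can reach 0.05.

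Gene lists, 43 in number, and the rule for genes to be named were fixed before the data were examined, as were the tests and the alternatives unless said otherwise. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg over the 43 lists. At that setting 14 passed, 5 higher and 9 lower. None passed with a correlation estimated per list, or with fry, which asks whether a list's genes move one way on balance. The genes named are the 10 largest rises and 10 largest falls among called genes with a gene-class symbol and at least 5 CPM in the higher group, the 2 largest each way among genes known by a sequence name, up to 3 called genes per passing list (or 2 as values where none was called), and 23 genes chosen in advance. One of these 23 is listed in the tables under its sequence name T24B8.5, and that alias was added after the tables were read. Gene ontology terms from the deposited tables were tested by Fisher's exact test against 9233 annotated tested genes (Python 3.11.15, scipy 1.17.1, 1020 terms per direction). That test, the split of embryo markers by stage, the thinning of libraries, the embryo score and the restriction to protein-coding genes were chosen after seeing the data.

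The steps were tested on simulated data for this comparison, with counts drawn for the real genes. Of 12309 genes tested there, the quasi-likelihood test recovered 62% of genes changed 2-fold and 90.7% of those changed 4-fold, and 11.2% of its calls were false, above the nominal 5%. A list of 30 genes raised 1.4-fold was recovered, and 0 of 40 unchanged lists were called. Genes were drawn independently there, so this does not test false list calls where the genes of a list vary together. Alternatives covered the scaling, the filter, the tool (DESeq2 1.42.0, limma-voom), the dispersion settings, a replicate block, each library left out, thresholds and the list test. Figures were drawn with matplotlib 3.10.9.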

Results

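RNA was sequenced from whole wild-type (N2) hermaphrodites of the nematode Caenorhabditis elegans, and the comparison asks which genes differ with the bacteria the worms were fed. The control food was OP50, the Escherichia coli strain on which laboratory worms are usually grown. The other food held the lactic acid bacterium Lactiplantibacillus sp. MH-1, and the sample labels name it together with OP50. Each group had 2 libraries. Total counts were 18485858 and 17593775 in the 2 libraries labelled OP50, and 15771890 and 21572225 in the 2 labelled OP50 + MH-1. Between 16557 and 17267 genes had at least 1 read in a library. The labels differ on the feeding: one text gives worms 4 days old fed for 1 day, and another gives worms 1 day old cultured for 2 days. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

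The direction of every difference depends on which label is right. In all 4 count tables the header of the count column names the other feeding group than the sample title does. Groups here follow the sample titles, and the text therefore speaks of libraries labelled OP50 or OP50 + MH-1. If the headers are right, each "higher" becomes "lower" with the same fold and the same p-value, and the counts alone cannot settle this.

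In the libraries labelled OP50 + MH-1, several genes of the cuticle and of embryos were higher, and several for lysosomal enzymes and fatty acid desaturation were lower. Of 12640 genes tested, 272 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 230 higher and 42 lower, with directions that reverse if the column headers are right. At least a 2-fold change was seen in 164 of them, 139 higher and 25 lower. The largest fall among named genes was comt-4, a predicted catechol-O-methyltransferase, at 56.8 ± 15.1 CPM (SD, n = 2) in the libraries labelled OP50 and 1.25 ± 0.333 CPM (SD, n = 2) in those labelled OP50 + MH-1. Its log2 fold change was -5.53 ± 0.27 (SE), with an adjusted p of 0.00203. The largest rise among named genes was ifa-3, an intermediate filament gene, from 0.423 ± 0.202 to 11.4 ± 6.62 CPM (SD, n = 2), a log2 fold change of 4.73 ± 0.57 (adjusted p = 0.0155, but 0.126 with limma-voom). In ce11 (WBcel235), comt-4 lies on chromosome V from 2049223 to 2050172 and ifa-3 on chromosome X from 16267257 to 16270056. All 272 called genes had both libraries of one group above both of the other. That held for 46.0% of all tested genes, where chance gives 33.3%. The number called depended on single libraries: 395 higher and 93 lower genes without OP50 replicate 1, 287 and 80 without OP50 replicate 2, 99 and 20 without OP50 + MH-1 replicate 1, and 223 and 95 without OP50 + MH-1 replicate 2. Of the 272 genes, 92 (77 higher, 15 lower) were called in all 4 of these fits. Each of the 4 fits leaves 1 library alone in its group, and the spread is taken from the other group. A p-value there, for a gene or a list, does not measure the spread of the reduced group. A test for a fold above 1.5 left 5 higher and 5 lower genes. With a score of embryo and molting markers as a covariate, added after the data were seen, 2 of the 230 higher and 9 of the 42 lower genes stayed called. That score includes called genes and separates the groups, so a loss of calls there does not tell embryo content from the feeding label.

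**Figure D1:**
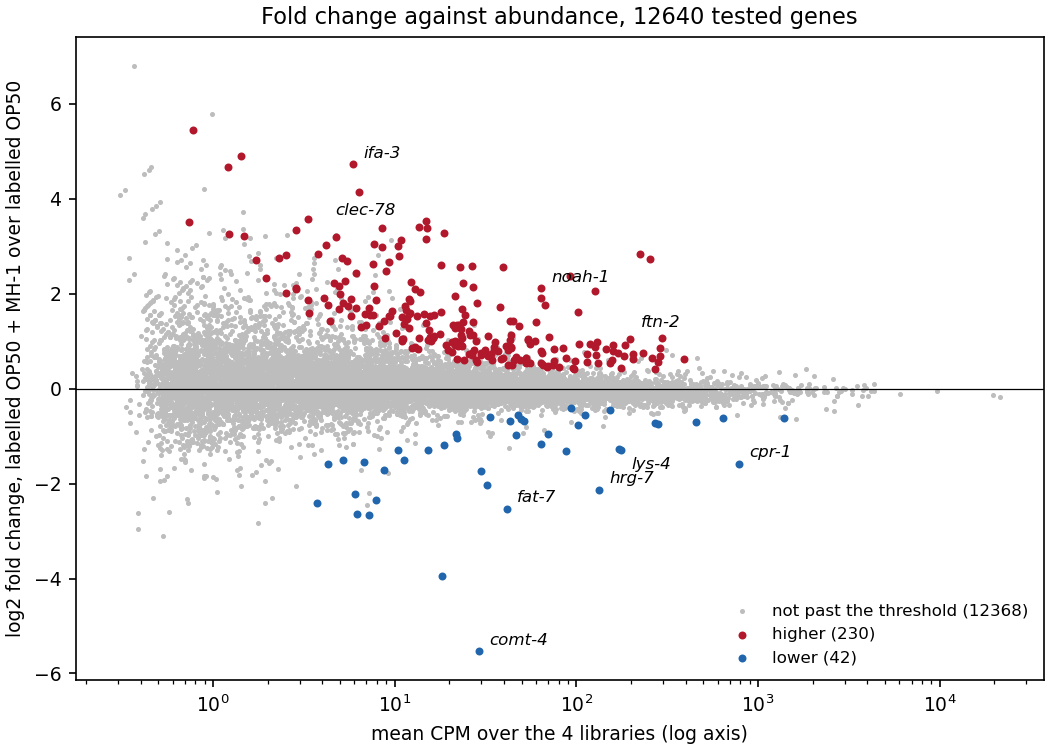
Log2 fold change of the libraries labelled OP50 + MH-1 over those labelled OP50 (vertical axis) against the mean CPM (normalised read count) over the 4 libraries on a log axis, 1 point per tested gene, with 230 genes called higher in red and 42 called lower in blue. The comt-4 point lies lowest, at -5.53, and the vertical axis turns over if the column headers are right.

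Several lysosomal and digestive proteases were lower in the libraries labelled OP50 + MH-1. Of 20 tested aspartyl and cathepsin-like proteases, 4 fell and none rose (9 adjusted over the list alone, 8 of them lower). The cathepsin B-like cpr-1 (chromosome V, 11975515 to 11976756) went from 1180 ± 31.3 to 394 ± 12.9 CPM (SD, n = 2), a log2 fold change of -1.58 ± 0.09 (SE, adjusted p = 0.00313). Its relative cpr-5 fell by 1.27 on the log2 scale, and the aspartyl protease asp-8 was 2.83-fold lower. The list stood apart by camera with a preset correlation (adjusted p = 5.66e-12), but not with an estimated one (adjusted p = 0.339 with an estimated correlation). The lysosomal acid ceramidase asah-1 changed by -2.03 ± 0.17 and the acid sphingomyelinase asm-2 by -1.51 ± 0.19. hrg-7, an aspartyl protease homologue in heme signalling, changed by -2.13 ± 0.19 (log2 ± SE). The list of 45 autophagy and lysosome genes, fixed in advance, did not shift: 21 were positive and 24 negative, with a median of -0.01, 1 higher and 1 lower gene called, and a camera adjusted p of 0.779. Among gene ontology terms tested after the data were seen, "lysosome" held 7 of the lower genes where 0.320 were expected (Fisher's exact test, one-sided, adjusted p = 2.32e-05). That test treats genes as independent, and the 7 include cpr-1, cpr-5, asah-1 and asm-2 from above, so it adds no separate support. Without OP50 + MH-1 replicate 1 the adjusted p of asp-8 was 0.105 and that of asm-2 0.0503, and without OP50 + MH-1 replicate 2 that of asp-8 was 0.0800. These directions, too, reverse under the headers' labels.

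Several fatty acid desaturases and a lipase were also lower in the libraries labelled OP50 + MH-1. The stearoyl-CoA desaturase fat-7 (chromosome V, 7151353 to 7153146) went from 70.8 ± 21.1 to 12.2 ± 3.47 CPM (SD, n = 2), a log2 fold change of -2.53 ± 0.25 (adjusted p = 0.00972). The second stearoyl-CoA desaturase fat-6 fell by 0.74, and the delta-6 desaturase fat-3 fell by 0.76 on the log2 scale. The fatty acid synthase fasn-1, named after its value was seen, rose by 0.73. Of 22 tested genes for fatty acid synthesis and desaturation, 3 fell and 1 rose (7 adjusted over the list alone, 6 lower). Camera gave an adjusted p of 7.44e-05 with the preset correlation, and an adjusted p = 0.339 with an estimated correlation. In fat breakdown, 2 of 35 genes fell, the lysosomal lipase lipl-3 (log2 fold change -2.34) and the peroxisomal oxidase acox-1.5 (-1.04) (10 adjusted over the list alone, all lower; camera adjusted p = 0.000172, and adjusted p = 0.339 with an estimated correlation). lipl-3 was also the called gene among 11 genes known to rise on fasting (7 adjusted over the list alone, 6 lower), a list with camera adjusted p = 0.000708 and adjusted p = 0.429 with an estimated correlation. That list's adjusted p was 0.100 without OP50 + MH-1 replicate 2. Without OP50 + MH-1 replicate 1 or 2, the adjusted p was 0.0501 or 0.0697 for fat-3, 0.0622 or 0.0835 for lipl-3 and 0.0995 or 0.102 for acox-1.5. With limma-voom it was 0.0732 for lipl-3 and 0.0676 for acox-1.5. Reads that fit both fat-6 and fat-7, which are close paralogs, may be assigned unevenly, since the handling of such reads is not given in the sources used here. All of these directions follow the titles and reverse under the headers.

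**Figure D2:**
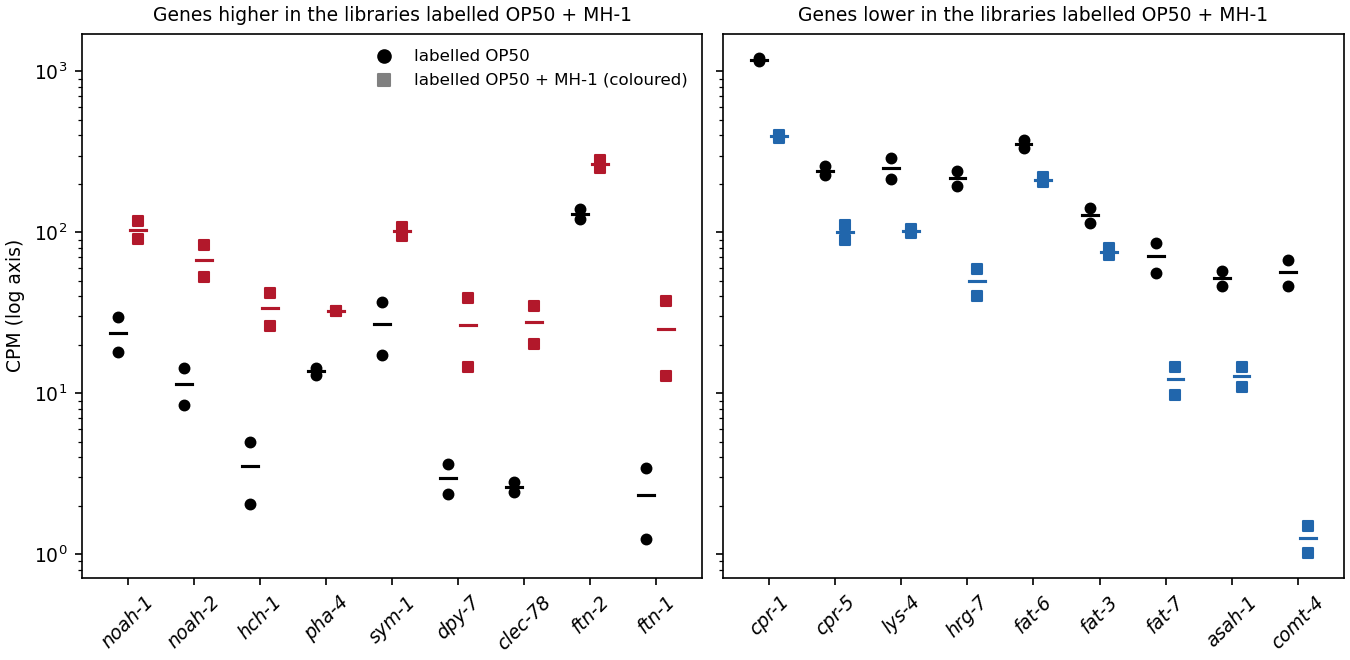
Normalised read count (CPM, log axis) of 9 genes called higher and 9 called lower in the libraries labelled OP50 + MH-1 (coloured squares) than in those labelled OP50 (black circles), 1 symbol per library, with a bar at each mean of 2 libraries. The 2 groups do not overlap in any of the 18 genes, as in all 272 called genes and in 46.0% of all tested genes. The cpr-1 symbols lie near 1180 CPM against 394 CPM, and the 2 groups exchange places if the column headers are right.

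Genes for antimicrobial proteins did not move as 1 block. The lysozyme lys-4 fell in the libraries labelled OP50 + MH-1, from 252 ± 51.4 to 102 ± 4.90 CPM (SD, n = 2), which is 2.47-fold lower (adjusted p = 0.0104). It was the 1 called gene of 12 tested lysozymes (6 adjusted over the list alone, 5 lower; camera adjusted p = 0.000311, and adjusted p = 0.545 with an estimated correlation). lys-7 stood at 178 and 203 CPM in the libraries labelled OP50 and at 182 and 176 CPM in the others, and did not pass. No caenopore or defensin-like gene of 17 passed (2 adjusted over the list alone, both lower), with spp-8 at a log2 fold change of -0.82 ± 0.15 (adjusted p = 0.0506) and spp-4 at -0.65 ± 0.14 (adjusted p = 0.0786). That list had camera adjusted p = 0.0355, adjusted p = 0.588 with an estimated correlation, 0.455 without OP50 replicate 2 and 0.786 without OP50 + MH-1 replicate 2. The log2 fold change of spp-8 was -1.03 without OP50 replicate 1 and -0.57 without OP50 replicate 2, fits that leave out the spread between the libraries labelled OP50. Of 78 C-type lectins, 2 rose and 1 fell, and the list did not pass (camera adjusted p = 0.582). clec-78 (chromosome IV, 3989102 to 4014195) rose from 2.62 ± 0.261 to 27.6 ± 10.6 CPM (SD, n = 2), a log2 fold change of 3.39 ± 0.30 (adjusted p = 0.00936). The other 2, clec-266 and clec-85, changed by 1.41 and -0.56 and were named after their values were seen. Of the 9 targets of the PMK-1 p38 immune pathway, 7 had a positive log2 fold change, with a median of 0.41. Their 1 called member, clec-85, was lower, while adjusted over the list alone 4 were higher and 1 lower. The list did not pass as higher (camera adjusted p = 0.0579), but did so without OP50 replicate 1 (0.0323) and without OP50 replicate 2 (0.0156). Under the column headers lys-4 is higher and clec-78 lower with MH-1.

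Cuticle and molting genes were among the genes higher in the libraries labelled OP50 + MH-1. Of 100 tested cuticle collagens, 14 rose and 1 fell (21 adjusted over the list alone, 19 higher). col-121 rose by a log2 fold change of 4.14 ± 0.53 and col-42 by 0.94 ± 0.13, while col-135 fell by 1.31. dpy-7, a collagen of the cuticle furrows (chromosome X, 7536417 to 7537792), went from 2.99 ± 0.896 to 26.7 ± 17.3 CPM (SD, n = 2). The list gave camera adjusted p = 1.13e-09, adjusted p = 0.588 with an estimated correlation, and 0.928 without OP50 replicate 2. The groups overlap in this list's mean: its log2 CPM deviated from each gene's mean over the 4 libraries by 0.43 and -1.14 in the libraries labelled OP50, and by 0.61 and 0.10 in those labelled OP50 + MH-1. The gene ontology term "collagen trimer" held 13 of the higher genes where 1.96 were expected (Fisher's exact test, one-sided, adjusted p = 3.39e-05). All 13 are called members of the collagen list, and the test treats genes as independent, so it adds no separate support. Of 13 larval molting genes, 4 rose and none fell (5 adjusted over the list alone). noah-1 and noah-2, proteins of the apical extracellular matrix of the epidermis, rose by 2.12 ± 0.23 and 2.57 ± 0.29, and mlt-11 by 2.56 ± 0.40 (log2 ± SE). That list gave camera adjusted p = 2.03e-07 and adjusted p = 0.339 with an estimated correlation. Of 41 hedgehog-related genes, wrt-10 rose by 2.59 and ptr-4 by 3.19 (3 adjusted over the list alone; camera adjusted p = 0.0307, adjusted p = 0.669 with an estimated correlation, 0.239 without OP50 replicate 2 and 0.146 without OP50 + MH-1 replicate 1). Without OP50 + MH-1 replicate 1 the adjusted p was 0.0844 for mlt-11 and 0.0966 for ptr-4. Software settings also ended calls here. With limma-voom the adjusted p was 0.123 for col-121, 0.161 for dpy-7, 0.0565 for wrt-10 and 0.227 for ptr-4. With robust dispersion (robust=TRUE) it was 0.0706 for noah-1, 0.090 for noah-2, 0.197 for mlt-11, 0.168 for dpy-7, 0.154 for wrt-10 and 0.0852 for ptr-4, and with legacy=FALSE it was 0.0990 for ptr-4. A score of the embryo and molting markers, the mean of their centred log2 CPM, was -0.39 ± 0.20 in the libraries labelled OP50 and 0.39 ± 0.16 in those labelled OP50 + MH-1 (SD, n = 2), and it turns with the labels as these genes do.

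**Figure D3:**
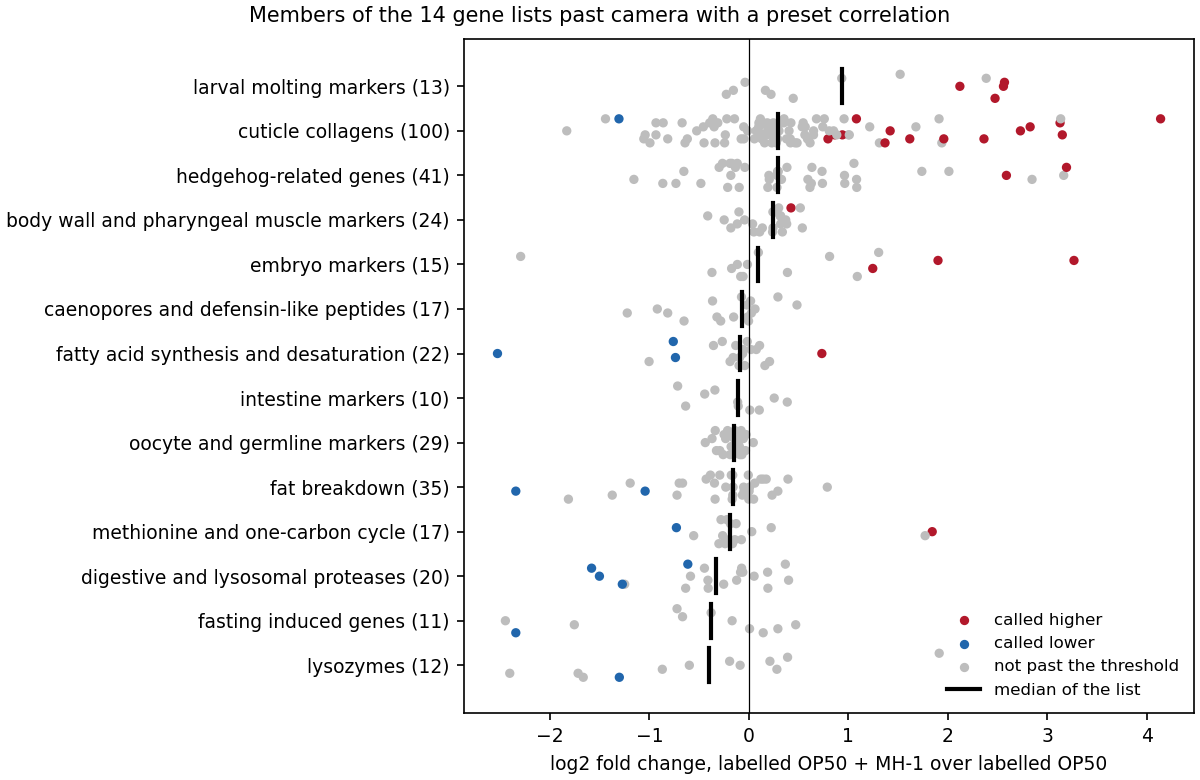
Log2 fold change, labelled OP50 + MH-1 over labelled OP50, of each tested member of the 14 gene lists that passed camera with a preset correlation, with called genes in red (higher) or blue (lower), other genes in grey and a black bar at each list's median; the number of members is in brackets. None of the 14 lists passed with an estimated correlation, and the horizontal axis turns over if the column headers are right.

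Some markers of embryos moved with the feeding labels. Of 15 tested embryo genes, 3 rose in the libraries labelled OP50 + MH-1 and none fell (6 adjusted over the list alone, 5 higher; camera adjusted p = 0.00129, and adjusted p = 0.429 with an estimated correlation). They were the hatching protease hch-1 (3.27 ± 0.40), the pharynx regulator pha-4 (1.25 ± 0.12) and sym-1 (1.90 ± 0.30), all as log2 fold change ± SE. The adjusted p of sym-1 was 0.0707 without OP50 + MH-1 replicate 1 and 0.0543 without OP50 + MH-1 replicate 2. With robust=TRUE it was 0.0917 for hch-1 and 0.224 for sym-1. Oocyte and germline markers had a negative log2 fold change in 28 of 29 genes, with a median of -0.15, but none passed alone or adjusted over the list alone (camera adjusted p = 2.93e-06, and adjusted p = 0.339 with an estimated correlation). puf-7 stood at -0.25 ± 0.08 and mex-5 at -0.34 ± 0.11. Of 24 muscle markers, pat-10, which encodes body wall muscle troponin C, rose by 0.42 ± 0.08 (6 adjusted over the list alone; camera adjusted p = 0.00533, adjusted p = 0.684 with an estimated correlation, 0.450 without OP50 replicate 2 and 0.155 without OP50 + MH-1 replicate 2). The call of pat-10 was lost without any 1 library: its adjusted p was 0.0635 and 0.178 without OP50 replicates 1 and 2, and 0.0637 and 0.0818 without OP50 + MH-1 replicates 1 and 2. It was also lost with limma-voom (0.0601) and with DESeq2 size factors (0.0525). None of 10 intestine markers passed (4 adjusted over the list alone, all lower), with asp-1 at -0.64 ± 0.15 and mtl-2 at -0.72 ± 0.15 (camera adjusted p = 0.0341, adjusted p = 0.588 with an estimated correlation, 0.112 without OP50 replicate 2 and 0.146 without OP50 + MH-1 replicate 1). For asp-1 the log2 fold change was -0.73 without OP50 replicate 1. The 6 vitellogenins, yolk proteins of the adult intestine, took 5.941% and 6.105% of counts in the libraries labelled OP50, and 4.268% and 7.055% in those labelled OP50 + MH-1. Neuron and sperm markers did not pass (camera adjusted p = 0.918 and 0.148). Every direction here follows the sample titles.

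**Figure D4:**
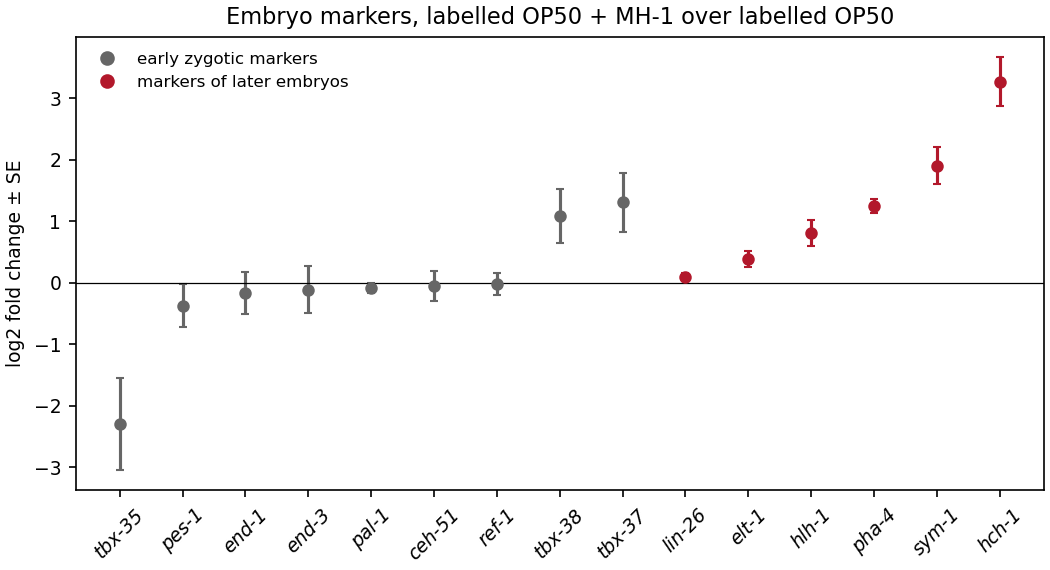
Log2 fold change ± SE of the 15 tested embryo markers, labelled OP50 + MH-1 over labelled OP50 (n = 2 libraries each). Grey marks 9 genes assigned to early zygotic markers and red marks 6 assigned to later embryos, a split made after the data were seen. The 6 later markers lie above 0, with hch-1 at 3.27, while 2 of the 9 early markers do; the axis turns over if the column headers are right.

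The metal and iron list, which mixes ferritin and transporter genes, and the one-carbon list each held members that moved in opposite directions. The ferritin gene ftn-1 rose in the libraries labelled OP50 + MH-1 by 3.41 ± 0.61, and ftn-2, named after its value was seen, by 1.04 ± 0.10, while the metal transporter smf-3 fell by 2.40 (log2 ± SE). These were the 3 called of 10 metal and iron genes (4 adjusted over the list alone, 2 each way), and the list did not move one way (camera adjusted p = 0.999). The adjusted p of ftn-1 was 0.0888 without OP50 + MH-1 replicate 1, and that of smf-3 was 0.0693 and 0.0859 without OP50 + MH-1 replicates 1 and 2. For ftn-1 it was 0.196 with limma-voom, 0.258 with robust=TRUE and 0.0561 with legacy=FALSE, and for smf-3 it was 0.0684 with limma-voom. In the methionine and one-carbon cycle, cystathionine gamma-lyase cth-1 rose from 5.33 ± 1.11 to 19.1 ± 3.87 CPM (SD, n = 2), and the phosphoethanolamine methyltransferase pmt-1 fell from 339 ± 13.6 to 205 ± 11.1 CPM. The list of 17 genes passed camera as lower (adjusted p = 0.0358, and adjusted p = 0.545 with an estimated correlation; 3 adjusted over the list alone, 2 higher), with a median of -0.19 and a mean of 0.02. The groups overlap in the list's mean, which deviated by -0.013 and -0.002 in the libraries labelled OP50, and by -0.062 and 0.078 in the others. Its adjusted p was 0.0985 without OP50 replicate 1, 0.112 without OP50 replicate 2, 0.0837 without OP50 + MH-1 replicate 1 and 0.0552 with total counts as the only scaling. With the groups exchanged as in the headers, ferritin genes are lower and smf-3 is higher.

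Most single genes chosen in advance did not pass, among them markers of stress and detoxification. Of these 23 genes, which also include immune, fat, yolk and muscle genes, 22 were tested and 20 did not pass. The exceptions were the fatty acid desaturases fat-6 and fat-7, described above. clec-60 was too low to test. The superoxide dismutase sod-3 stood at 1.41 ± 0.567 and 1.53 ± 0.582 CPM, the chaperone hsp-4 at 493 ± 8.99 and 457 ± 32.4 CPM, and acdh-1, a dehydrogenase repressed by vitamin B12, at 875 ± 54.4 and 932 ± 72.2 CPM (SD, n = 2; labelled OP50 first). The mitochondrial chaperone hsp-6 had a log2 fold change of -0.11 ± 0.11 (SE). The regulators daf-16, skn-1 and pmk-1 had log2 fold changes of -0.27 ± 0.09, -0.27 ± 0.11 and 0.17 ± 0.12 (SE). Close to the threshold were fat-5, at 44.5 ± 13.4 and 22.2 ± 1.58 CPM (adjusted p = 0.0609), and fmo-2, at a log2 fold change of -2.45 ± 0.51 (adjusted p = 0.0745). fat-5 passed without OP50 replicate 1 (0.000116) and OP50 replicate 2 (0.0376), and fmo-2 passed without OP50 replicate 1 (8.09e-06), with both passing when libraries were scaled by total count alone. The small heat shock gene hsp-16.2 stood at 71.5 and 9.79 CPM in replicates 1 and 2 labelled OP50. In those labelled OP50 + MH-1 it stood at 95.4 and 16.52 CPM, so replicate 1 was the higher in both groups. Its log2 fold change was 0.45 with all libraries and 2.50 without OP50 replicate 1, a fit that mixes feeding with the replicate number. T24B8.5, a readout of the p38 pathway, stood at 75.7 ± 31.4 and 94.1 ± 0.694 CPM (SD, n = 2) and did not pass. Its log2 fold change was 0.31 ± 0.24 (SE), and 0.81 without OP50 replicate 1, a fit that leaves out the wide spread between the libraries labelled OP50. irg-4, mtl-1, gst-4, vit-2, acs-2, lgg-1, sqst-1 and unc-54 had log2 fold changes between -0.71 and 0.22 and did not pass. Among lists, cytosolic heat shock genes (camera adjusted p = 0.291) and mitochondrial stress genes (0.288) did not pass. Neither did endoplasmic reticulum stress genes (0.918) or glutathione S-transferases (0.288). The heat shock list passed as lower without OP50 replicate 2 or without OP50 + MH-1 replicate 1. However, its mean log2 CPM followed the replicate number in both groups. It deviated by 0.66 and -0.66 in replicates 1 and 2 labelled OP50, and by 0.72 and -0.72 in the others. Those passes therefore do not tell feeding from the replicate number. SKN-1 detoxification genes (0.0582) and cytochrome P450 genes (0.0509), both with a negative median, also did not pass, and neither did DAF-16 activated genes (0.142, median -0.15). The SKN-1 list passed without OP50 replicate 2 (0.0287), without OP50 + MH-1 replicate 1 (0.0144) and with total counts as the only scaling (0.0485). The P450 list passed with total counts as the only scaling (0.0229), and also without OP50 replicate 1. The DAF-16 list passed as lower without OP50 replicate 2 and without OP50 + MH-1 replicate 1, but it too followed the replicate number. Its mean log2 CPM deviated by 0.26 and -0.23 in replicates 1 and 2 labelled OP50, and by 0.40 and -0.42 in the others.

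Further genes named by size of change were the following, as log2 fold change of the libraries labelled OP50 + MH-1 over those labelled OP50 ± SE. Higher were dsl-6 (3.58 ± 0.64), the linker histone hil-7 (3.52 ± 0.49), the transcription factor hlh-16 (3.35 ± 0.35), R09E10.5 (3.37 ± 0.38) and C14F11.6 (2.98 ± 0.46). Lower were Y41C4A.32 (-3.94 ± 0.60), T16G1.7 (-2.67 ± 0.49) and the trehalase tre-5 (-1.55 ± 0.26). Without OP50 + MH-1 replicate 1 the adjusted p was 0.132 for dsl-6, 0.0767 for C14F11.6, 0.0643 for Y41C4A.32, 0.147 for T16G1.7 and 0.132 for tre-5. Without OP50 + MH-1 replicate 2 it was 0.0941 for Y41C4A.32, 0.132 for T16G1.7 and 0.0886 for tre-5, and without OP50 replicate 2 it was 0.0508 for tre-5. With limma-voom it was 0.203 for dsl-6, 0.151 for hil-7, 0.0577 for R09E10.5, 0.0755 for C14F11.6, 0.175 for Y41C4A.32, 0.175 for T16G1.7 and 0.0659 for tre-5. With robust=TRUE it was 0.0628 for dsl-6, 0.136 for hil-7, 0.0697 for C14F11.6, 0.246 for Y41C4A.32 and 0.101 for T16G1.7, and with legacy=FALSE it was 0.0950 for dsl-6 and 0.0759 for T16G1.7. The signs reverse if the column headers are right.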

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

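The embryo score, the thinning and the restriction to protein-coding genes were chosen after seeing the data. Of 12640 genes tested, 2.15% were called (230 higher, 42 lower), and 1.3% were called at least 2-fold. Counts stayed within 1.5 times of these under other scaling factors, a stricter filter, robust or newer dispersion settings, thinning, protein-coding genes only and removal of abundant genes, and no called gene changed sign in any setting except the embryo score. With no filter, where more genes were tested, 5.63% were called (815 higher, 297 lower), 2.54% at least 2-fold. DESeq2, which left 1226 genes without an adjusted p, called 3.67% (369 and 95), 2.06% at least 2-fold, and limma-voom 1.28% (135 and 27), 0.72% at least 2-fold. An adjusted p under 0.01 left 0.222% (22 and 6), 0.15% at least 2-fold, and a test for a fold above 1.5, which asks for more by construction, left 0.0791% (5 and 5), 0.0791% at least 2-fold. Leaving out 1 library gave 0.906% to 3.68% (99 to 395 higher, 20 to 95 lower), and 0.533% to 2.61% at least 2-fold; the lone library is then assumed to vary like the other group. The replicate block gave 4.42% (450 and 109), 2.32% at least 2-fold; same-numbered libraries deviated together by a correlation of 0.209 across genes, over only 2 pairs, and no label says that the numbers pair libraries. With the embryo score as a covariate 0.823% were called (24 and 80), 0.823% at least 2-fold, with 2 of the 230 higher and 9 of the 42 lower genes among them; the score separates the groups, leaving little residual information. Under it the log2 fold changes of wrt-10 (-0.20), C14F11.6 (-0.24), mlt-11 (-0.26), ftn-1 (-1.38) and hsp-16.2 (-7.66) reversed. The cause of the other shifts was not tested. List calls numbered 14, and 0 with an estimated correlation and 0 by fry. Of the 14 lists, 13 also passed with the replicate block, and the methionine and one-carbon list did not. Several of the 14 lost the call when 1 library was left out, as given for each list above. Over the fits without 1 library, the vitellogenin list had adjusted p from 8.76e-07 to 0.726 and reversed without OP50 + MH-1 replicate 1 (0.0213). The ribosomal protein list had 0.00289 to 0.0174 and reversed without OP50 replicate 2 (0.0165) and without OP50 + MH-1 replicate 1 (0.00409). Named genes kept direction and side of the threshold in 1079 gene-by-setting comparisons, lost the call in 127 and gained one in 35; lists did so in 359, 43 and 25. A change of sign with no call on either side, 53 in all, counts as kept. Depth limits genes near 3 counts, between 0.139 and 0.190 CPM.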

Other observations

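The gene ontology tests, the thinning, the embryo score, the split of embryo markers, the ratios between replicates and the tests of marker medians below were chosen after results were seen. Some groups not described above also held called genes. Fisher's exact test, used for the terms here, treats genes as independent, so its p-values can be too small where genes vary together. Among the higher genes, 8 carried the gene ontology term for RNA polymerase II transcription factor activity where 1.80 were expected (adjusted p = 0.0363), among them ceh-27, ceh-32, sox-2 and hbl-1. Nervous system development held 8 where 1.67 were expected (adjusted p = 0.0251), and the laminin genes lam-1, lam-2 and lam-3 were among 4 called genes of tissue development. The insulin-regulated dod-24 was lower, from 92.3 ± 7.55 to 47.9 ± 4.19 CPM (SD, n = 2). It was the 1 called of 8 tested DAF-16 repressed genes, a list with 4 positive and 4 negative members, a median of 0.03 and a camera adjusted p of 0.184. All of these directions follow the sample titles.

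The genes higher in the libraries labelled OP50 + MH-1 may come in part from more or older embryos inside or beside the worms. Markers assigned to later embryos had a median log2 fold change 1.11 above that of markers assigned to early ones (1.03 for 6 genes against -0.08 for 9, exact two-sided permutation test of the means, p = 0.0228). However, 3 of the later markers are themselves called genes, and without them the difference was 0.47 (3 genes against 9, exact two-sided permutation test of the means, p = 0.409), so this test left the explanation open. Within each group the higher genes also differed together between the 2 libraries, with a median log2 ratio of replicate 1 to 2 of 0.152 in the group labelled OP50 + MH-1 and 0.153 in the other, outside the ranges of random gene sets (-0.03 to 0.04 and -0.02 to 0.03). Any genes regulated together could do so, and the ratio has the same sign in both groups, so this does not test embryo content. Both tests were first read as support, and their rules were tightened after their values were seen. With the embryo score as covariate the median of these genes went from 1.22 to 0.63 and 2 of 230 stayed called, but the score was built from genes that include called ones and separates the groups, so this fit does not tell embryo content from the feeding label. Sequencing depth is argued against, since 221 of the 230 stayed called after thinning to one depth; a direct effect of the food on cuticle genes stays open and was not tested.

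The genes lower in the libraries labelled OP50 + MH-1 could be adult transcripts diluted by embryo RNA, and 2 marker sets were tried for this. The first, 10 intestine markers, left it open: their median was -0.11 against -1.28 for the lower genes, a gap of 2.80 times their median absolute deviation, short of the bound of 3 set for it. The 6 vitellogenins were chosen only after that result; their median was also -0.11, and the gap was 3.66 times their largest standard error, over a bound of 3. Their median ranged from -0.49 without OP50 + MH-1 replicate 2 to 0.21 without OP50 + MH-1 replicate 1, against -1.34 and -1.11 for the lower genes in these fits. The gap was under the bound without OP50 replicate 2 (2.68 times) and without OP50 + MH-1 replicate 2 (2.83 times), and over it in the other 2 fits. The lower genes were picked for their fall in these same data, so a set not picked that way tends to lie above them whatever the cause. The vitellogenin gap was also a second attempt and did not pass that bound in each fit. Neither gap therefore decides on dilution for the lower genes as a set, where it stays open. Among the largest falls, comt-4 (-5.53 ± 0.27) and cpr-1 (-1.58 ± 0.09, log2 ± SE) stayed called in all 19 other settings. The vitellogenin median stayed between -0.49 and 0.21 in the fits above. For comt-4 and cpr-1 these values argue against dilution as the whole cause, and dilution as a part of it stays open. Depth is argued against, with 41 of 42 called after thinning, and an effect of the food on these genes was not tested.

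The direction of every change rests on labels that disagree. If the 2 groups' files were exchanged when deposited, all directions could be reversed: the number of files whose header names the other group was 4 of 4, and no value in the tables tells the titles' order from the headers' order, so the explanations cannot be told apart.

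A candidate explanation for higher ftn-1 and ftn-2 with lower smf-3 is lower activity of HIF-1, which represses ferritin genes. The prediction set for it was a fall of the 9 hypoxia response genes, and whether they must fall with it was not tested. Instead 8 of 9 had a positive log2 fold change, with a median of 0.20, a mean of 0.49 and a standard deviation of 0.62. The list did not pass as higher (camera adjusted p = 0.0582), but did so without OP50 replicate 1 (0.0192), without OP50 + MH-1 replicate 2 (0.0255) and after thinning (0.0498), and not with an estimated correlation (0.588). The bound for excluding the explanation was first a median above 0, which this value meets. It was raised, after the value was seen, to a median above 0 by more than that standard deviation, which the value does not meet. These values go against that prediction without excluding the explanation by the later bound, and the explanation stays open.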
